A study of Mus musculus with 3 samples.

How the data were processed

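Transcription start sites were mapped by nanoCAGE, which captures the capped 5' ends of mRNAs by template switching and sequences them. The cells were BM67 mouse prostate cancer cells, a PTEN-deficient line from the PB-Cre;PtenFlox/Flox model, with a stable pGIPZ vector expressing an shRNA against mouse ERα. Per the labels, 3 biological replicates form 1 group, with 2 barcodes for each. The series text gives cytosolic mRNA as the input, while the sample labels give total RNA. No control cells are among the samples analysed here, so no comparison between groups was made. The comparisons are between classes of mRNA within these cells.

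The deposited table gives, for each RefSeq transcript, the count of mapped reads, a read-weighted mean 5' UTR length, the 5' UTR length at the start site with the most reads, and the 5' UTR sequence from that site. The read counts are not normalised, per the file headers and the whole numbers they hold. Per the submitters' processing notes, cutadapt version 1.9.1 and Bowtie version 0.12.7 were used with the mm10 build. TagDust split the barcodes, per the labels. The rule that assigned a read to a transcript and the treatment of reads with several mapping places are not given in the sources used here. The table has 1 column per measure and no column per replicate, so it was read as the authors' pooled values. How replicates and barcodes were combined is not stated in the sources used here. No replicate error can be given for any value, and no test between replicates was run.

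The table held 8930 transcripts of 8749 genes, and no transcript had fewer than 10 reads. Reads summed to 5880490 over transcripts. For 144 genes with more than 1 transcript, each transcript of a gene listed the same number of reads. For these the transcript that came first in alphabetical order of its ID was used, leaving 5795807 reads over genes. A gene had a median of 220 reads, with quartiles of 76 and 592. PCR copies were not separable, so read numbers are not numbers of molecules. Every mean length multiplied by its read number came out whole within 0.01. The length at the highest peak differed from the sequence length by at most 0.5 nt, in 103 transcripts. Gene symbols and gene coordinates came from the RefSeq gene table of assembly GRCm38.p6, the assembly of mm10, by Entrez gene ID. A symbol was found for 8748 gene IDs and not for the remaining 1.

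From each sequence the GC content, the minimum free energy at 37 degrees C (RNAfold version 2.7.2), the first bases and the upstream AUGs were computed. The free energy had been planned to come from the table, which holds sequences and no energies. A 5' TOP start was defined as a C at base 1 followed by at least 4 pyrimidines. An upstream AUG was any AUG inside the 5' UTR, in any frame. Each was also classed by whether an in-frame stop codon followed inside the 5' UTR.

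The gene lists, the tests and the rule for naming genes were set before the data were examined. There were 29 lists, of which 27 had at least 5 genes in the table and were compared. One further listed name matched no gene ID. The median of a list was placed among the medians of 10000 random lists with the same number of genes. Random lists for length, GC content and folding energy were matched on 10 bins of read number, and folding energy was also compared with lists matched on 20 bins of length. Shares of TOP starts and of upstream AUGs were compared with unmatched random lists, and those of upstream AUGs also with lists matched on 20 length bins. A list stood apart when its percentile was below 1 or above 99, which for medians chance gives for 2% of lists, or 0.54 of 27. For shares, which take few values, this rate need not hold. For example, 75 genes without a TOP start stood only at percentile 11.0, so a low call was out of reach there. Genes are not replicates, so percentiles describe these libraries and no p-value was computed. The genes named are Esr1 and Pten, then the shortest, middle and longest member of each list that stood apart in length, and the lowest and highest members for other features, for at most 30 genes per feature. The 3 shortest and 3 longest members of the U34, stress-translated and eIF4E-sensitive lists, and of all genes with at least the median number of reads, are also named. Genes outside this rule were chosen after their values were seen, and the text says so at each place.

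The list comparison was tested on simulated lists drawn from the 8749 genes, 200 lists per setting. Multiplying the lengths of a list by 0.5 led to a call in 24.5% of lists of 10 genes, 56.0% of 20 genes, 91.5% of 40 genes and 100% of 80 genes. With a factor of 0.8 it led to a call in 5% of lists of 10 genes and 27.5% of lists of 80 genes. Small lists that did not stand apart therefore leave open differences of this size. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

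The alternatives tried were the longest or shortest transcript per gene, genes with at least 220 reads, leaving out 5' UTRs under 20 nt or over 1000 nt, means in place of medians, leaving out 49 genes found in more than 1 list, matching on GC content, on length, or on length with 5 bins of GC content, energy divided by length, and stricter or wider definitions of TOP starts and upstream AUGs. Unmatched random lists, matching of shares on reads, matching of upstream AUGs on 20 bins of length with 5 bins of reads, the length at the highest peak and TOP shares without ribosomal protein genes or without genes of both TOP lists were added after the data were seen. A comparison with annotated 5' UTR lengths, a count of start sites per gene and replicates left out in turn were planned only where the data allowed them and were not run.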

Results

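The 5' ends of mRNAs were mapped by nanoCAGE in BM67 mouse prostate cancer cells that carry an shRNA against the estrogen receptor ERα. The deposited table has 1 value per transcript for 3 replicates. It was read as the authors' pooled values, how replicates and barcodes were combined is not stated in the sources used here, and no replicate error can be given. The table covered 8749 genes with 5795807 reads, and a gene had between 10 and 74272 reads. The questions addressed are which classes of mRNA carry short or long, structured, TOP-starting or AUG-containing 5' UTRs in these cells.

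Esr1, the gene that encodes ERα and the target of the shRNA, was listed with 49 reads, under the lower quartile of 76 over all genes. Its mRNA (Entrez gene 13982, chromosome 10, 4611989 to 5005633 in GRCm38) had a mean 5' UTR of 335.1 nt with 4 upstream AUGs, each followed by an in-frame stop codon inside the 5' UTR. No control cells were analysed here, so the extent of the knockdown was not measured. Pten, the tumour suppressor deleted in this line, was not among the listed genes, where the lowest number of reads was 10. Its absence cannot be tied to the deletion, because Tpi1 of the glycolysis list and Psmc2 of the proteasome list were not listed either. Both were chosen after the data were seen. For any gene, not being listed does not show lack of expression. Ar, the androgen receptor, had 279 reads.

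Markers of luminal prostate epithelium were listed for 6 of 14 genes and included Krt8 with 38292 reads and Krt18 with 19579 reads, both keratins of simple epithelia, and Hoxb13 with 366 reads. Cdh1, Epcam and Nkx3-1 were among the 8 not listed. Basal markers were listed for 5 of 12 genes, with Krt14 at 3346 reads and Cd44 at 1127 reads, while Krt5 and Trp63 were not listed. Of the fibroblast and stromal markers 4 of 14 were listed. Vim, an intermediate filament that many cultured cells also express, had 22808 reads, and Fbln1, Col3a1 and Pdgfra had 104, 71 and 31 reads. Of 16 immune and endothelial markers only Cd68 was listed, with 90 reads. The marker genes named in this paragraph were chosen after their values were seen.

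Over all genes the mean 5' UTR length had a median of 108.7 nt, with quartiles of 53.5 and 205 nt. Lengths under 30 nt were found for 1144 genes (13.1%) and lengths over 500 nt for 368 genes (4.21%). Among genes with at least 220 reads the shortest were Prkaa1 (3.56 nt), a catalytic subunit of AMPK, Fmo1 (7.08 nt) and Suclg1 (8.01 nt). The longest were Rptor (1985 nt, chromosome 11, 119602905 to 119899591), the defining subunit of mTOR complex 1, Flna (1953 nt), an actin crosslinker, and Gprasp1 (1441 nt). Rptor carried 32 upstream AUGs and Flna 41.

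Short 5' UTRs were found in mRNAs for ribosomes, mitochondrial energy production and protein synthesis. Cytosolic ribosomal protein mRNAs had a median length of 43.0 nt, against 93.4 nt in random lists of like read number, and 74 of 79 lay below the median of all genes. Mitochondrial ribosomal protein mRNAs were shorter still at 28.3 nt, with 66 of 75 below that median, and mRNAs for oxidative phosphorylation had 46.8 nt, with 70 of 76 below it. All of these lay below all 10000 random lists. Rpl13a (19.1 nt), Rpl13 (43.0 nt) and Rpl31 (240.1 nt) were the shortest, middle and longest of the cytosolic ribosomal proteins. Mrps26 (10.0 nt), Mrpl17 (28.3 nt) and Mrps17 (300.8 nt) held these places among the mitochondrial ones. Ndufb5 (11.1 nt), Ndufs8 (43.6 nt) and Ndufv2 (430.7 nt), subunits of respiratory complex I, held them for oxidative phosphorylation.

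Further lists with short 5' UTRs were translation initiation factors (55.7 nt in 37 genes, percentile 0.16), the proteasome (52.4 nt in 32 genes, percentile 0.17), enzymes that modify the wobble uridine U34 of tRNAs (43.5 nt in 16 genes, percentile 0.24), DNA replication (65.2 nt in 46 genes, percentile 0.38) and aminoacyl-tRNA synthetases (53.9 nt in 23 genes, percentile 0.655). Initiation factors ranged from Eif3f (14.8 nt) through Eif2b3 (55.7 nt) to Eif4g3 (458.0 nt), and proteasome subunits from Psmc1 (8 nt) through Psmb3 (49.8 nt) to Psma7 (894.4 nt). Of the U34 enzymes the shortest were Mocs3 (15.2 nt), Urm1 (15.7 nt) and Elp4 (19.0 nt), and the longest were Elp5 (157.8 nt), Elp1 (161.6 nt) and Trmt112 (272.2 nt). Of the 16 U34 genes 13 lay below the median of all genes. Initiation factors did not stand apart without genes shared with other lists (30 genes, percentile 80.7), without 5' UTRs under 20 nt (26.98), with means (2.98) or at the highest peak (1.82). Synthetases did not with genes of at least 220 reads (percentile 1.71), without 5' UTRs under 20 nt (6.98) or at the highest peak (4.12), nor did the 6 U34 genes of at least 220 reads (2.25).

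Long 5' UTRs were found in 6 lists. Of 50 receptor tyrosine kinases and growth factors 23 were listed, and of 39 nuclear receptors 18 were. All of these lay above the median of all genes, with list medians of 264.8 nt (percentile 99.99) and 251.8 nt (percentile 99.85). Listed members numbered 24 of 35 for estrogen response genes and 56 of 75 for chromatin regulators. Estrogen response genes had 243.4 nt, with 18 of 24 above the median (percentile 99.97), and chromatin regulators 175.5 nt, with 40 of 56 above it (percentile 99.92). Growth factors ran from Bmp4 (125.3 nt) through Hbegf (264.8 nt) to Tgfb3 (1054 nt), and nuclear receptors from the vitamin D receptor Vdr (128.4 nt) through Ppard (245.2 nt) to Ar (1021 nt, chromosome X, 98148757 to 98323218). Estrogen response genes ran from Xbp1 (21.9 nt), a transcription factor of the unfolded protein response, through Cited2 (242.2 nt) to Nrip1 (736.2 nt), a corepressor of nuclear receptors. Chromatin regulators ran from Kat8 (10.98 nt) through Brd3 (172.6 nt) to Kdm2a (825 nt). Kdm2a rested on 22 reads, and its mean length equalled its peak length. With genes of at least 220 reads, estrogen response genes (percentile 91.8), nuclear receptors (percentile 98.2, 6 genes left) and chromatin regulators (percentile 98.5) did not stand apart.

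mRNAs whose translation is known to depend on the cap-binding protein eIF4E had a median of 251.8 nt, and 16 of 17 lay above the median of all genes (percentile 99.96). The longest were the apoptosis inhibitor Bcl2 (1390 nt), the angiogenic growth factor Vegfa (1013 nt) and Birc2 (959.4 nt). The shortest were Birc5 (34.1 nt), Nbn (118.6 nt) and Ccnd1 (131.9 nt). mRNAs translated under stress had 238.2 nt in 13 genes (percentile 99.77), from Uchl1 (51 nt), Eprs (117.7 nt) and Hspa5 (147.7 nt) to Cebpb (508.3 nt), Ibtk (535.2 nt) and Slc35a4 (622.7 nt). Both lists were assembled from mRNAs known for their 5' UTRs, so their lengths are not independent of how they were chosen. The length of Cebpb depends on the start codon of its RefSeq transcript, since 2 upstream AUGs were in frame without a stop. Bcl2 and Uchl1 rested on 41 and 13 reads. Against random lists matched on GC content the stress-translated list stood at percentile 98.7, and without shared genes 7 eIF4E-sensitive mRNAs stood at 98.95.

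The other 13 lists did not stand apart in length. They included androgen response genes (101.0 nt in 23 genes, percentile 50.6), glycolysis (91.7 nt in 18 genes), cholesterol synthesis (87.8 nt in 27 genes), the spliceosome (93.8 nt in 41 genes), chaperones (80.8 nt in 41 genes), mitosis genes (132.2 nt in 48 genes) and PI3K-AKT-mTOR signalling (166.8 nt in 31 genes, percentile 98.2). Other known TOP mRNAs had 73.6 nt in 20 genes (percentile 15.0), and patterning transcription factors 122.1 nt in 37 genes (percentile 68.9). Polyamine pathway genes had 159.5 nt in 9 genes, and the list of iron responsive element mRNAs 167.2 nt in 5 genes. Luminal markers had 80.2 nt in 6 genes and basal markers 118.9 nt in 5 genes. With means of log2 length in place of medians, PI3K-AKT-mTOR signalling (percentile 99.6) and patterning transcription factors (percentile 99.7) stood apart as long, and at the highest peak, an alternative chosen after the data were seen, PI3K-AKT-mTOR signalling did too (percentile 99.3).

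**Figure D1:**
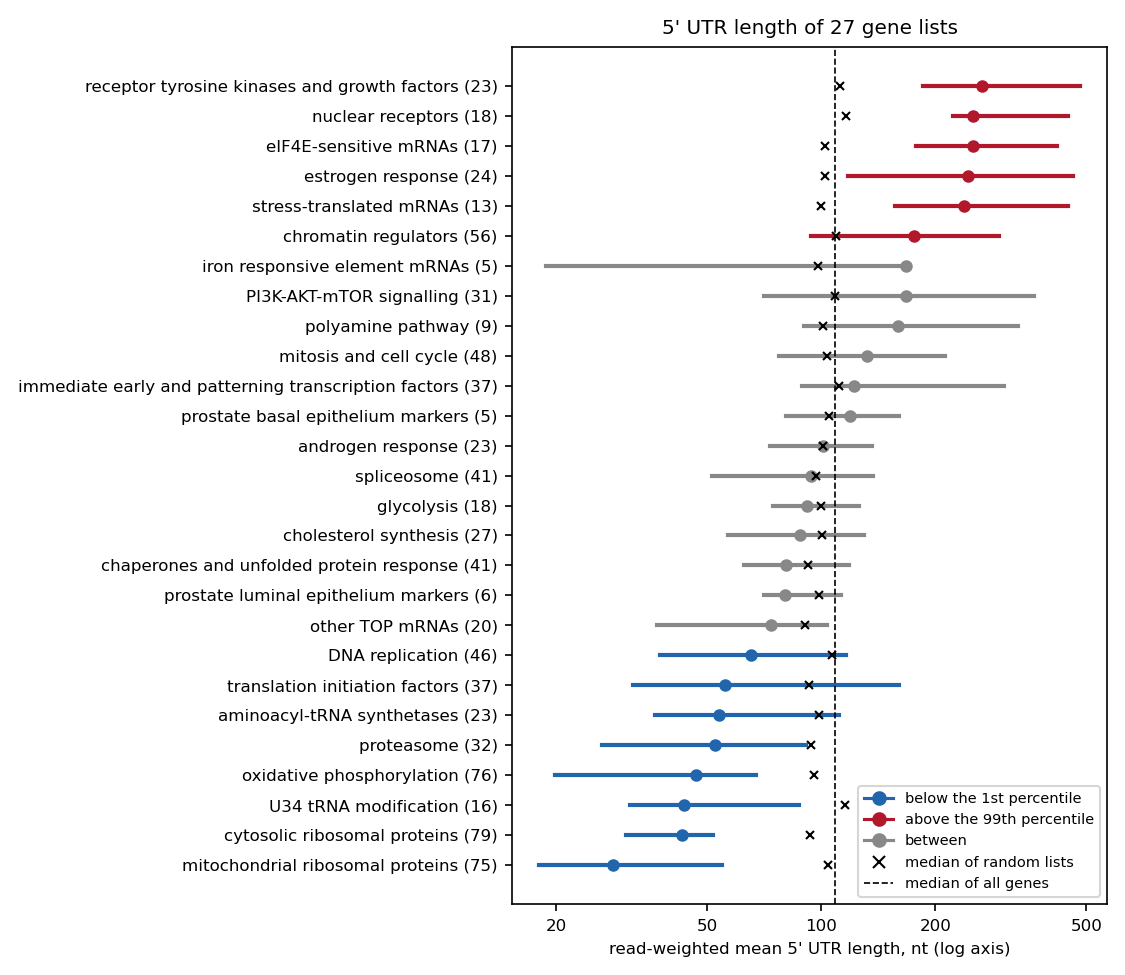
Read-weighted mean 5' UTR length in nt on a log axis for 27 gene lists, with the number of genes in brackets, where points are list medians, bars span the quartiles over genes and crosses are medians of random lists of like read number. The 8 short lists have medians of 28.3 to 65.2 nt and the 6 long lists 175.5 to 264.8 nt, on either side of the dashed median of all genes at 108.7 nt.

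GC content set few lists apart. The 5' UTRs over all genes had a median GC content of 65.4%, and only mRNAs for oxidative phosphorylation stood apart, at 62.1% against 66.0% in random lists (percentile 0.25), with 49 of 76 below the median of all genes. Their lowest and highest members were Ndufa2 (40%) and Ndufb9 (75%), both complex I subunits. Chaperones lay highest, at 69.4% (percentile 98.3), and did not stand apart. The call for oxidative phosphorylation ended without 5' UTRs under 20 nt (percentile 5.37, 51 genes) and with unmatched random lists (percentile 1.38).

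Predicted folding followed length. More stable 5' UTRs, with lower free energies than random lists, were found for receptor tyrosine kinases and growth factors (median −105.7 kcal/mol), eIF4E-sensitive mRNAs (−101.9), estrogen response genes (−101.7), nuclear receptors (−89.5), stress-translated mRNAs (−82.2), PI3K-AKT-mTOR signalling (−77.2) and chromatin regulators (−76.3), against −39 over all genes. Less stable ones were found for mitochondrial ribosomal proteins (−5.2), cytosolic ribosomal proteins (−7.7), U34 enzymes (−10.9), the proteasome (−11), oxidative phosphorylation (−11.2), initiation factors (−17.3) and DNA replication (−20.5). The most stable members included Rptor (−780.5 kcal/mol), Tgfb2 (−471.0), Vegfa (−459.8), Kdm2a (−403.7), Psma7 (−393.5), Adcy9 (−375.0) and Ar (−352.1). Kdm2a and Adcy9 had only 22 and 36 reads. Rps17, Xbp1, Urm1, Prkaa1 and Mrps7 had 0 kcal/mol, with 5' UTRs of at most 16 nt at the highest peak. Calls of less stable lists ended for initiation factors without shared genes (percentile 66.8), without 5' UTRs under 20 nt (92.99), with means (95.2) and with energy divided by length (94.3), for U34 enzymes and DNA replication with genes of at least 220 reads (96.1 and 98.1), for DNA replication with energy divided by length (89.2) and for the proteasome with means (97.8). Calls of more stable lists ended for estrogen response genes, nuclear receptors and chromatin regulators with genes of at least 220 reads (percentiles 8.15, 7.86 and 2.32), for PI3K-AKT-mTOR signalling without 5' UTRs over 1000 nt (9.46), for nuclear receptors and eIF4E-sensitive mRNAs without shared genes (1.46 and 1.535), for nuclear receptors and stress-translated mRNAs without 5' UTRs under 20 nt (1.315 and 1.25), for stress-translated mRNAs with the shortest 5' UTR per gene (1.005) and with unmatched lists, chosen after the data were seen (2.33), and with energy divided by length for estrogen response genes (9.39), nuclear receptors (31.0), stress-translated mRNAs (61.4), eIF4E-sensitive mRNAs (1.27) and receptor tyrosine kinases and growth factors (1.07).

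Matching on length removed all but 1 of these 14 calls. Cytosolic ribosomal protein mRNAs had −7.7 kcal/mol against −10.2 in random lists of like length (percentile 99.9), from Rps19 (−119.9) to Rps17 (0). Receptor tyrosine kinases and growth factors stood at percentile 43.5, eIF4E-sensitive mRNAs at 27.5 and mitochondrial ribosomal proteins at 70.7. Cytosolic ribosomal proteins did not stand apart with means (percentile 95.2). With matching on length and GC content together they did not either (percentile 96.2), and 5 basal markers, which had not stood apart before, stood at 99.8.

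Across the 8749 genes, length at the highest peak and folding energy had a Spearman coefficient of −0.97 and a Pearson coefficient of −0.96. Length and GC content had a Spearman coefficient of −0.16 and a Pearson coefficient of −0.19, and GC content and folding energy −0.0079 and 0.038. Divided by length, folding energy had Spearman coefficients of −0.51 with GC content and −0.55 with length. These 5 relations were computed across genes, which are not independent replicates.

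Starts with a 5' TOP sequence, the mark of mRNAs whose translation follows mTOR activity, were more frequent than in random lists in 4 lists. Of cytosolic ribosomal protein mRNAs 37 of 79 (46.8%) and of other known TOP mRNAs 9 of 20 (45.0%) started with one, against 178 of 8749 genes (2.03%). Translation initiation factors followed with 6 of 37 (16.2%, percentile 99.99), of which 3 were also among the other known TOP mRNAs, and androgen response genes with 3 of 23 (13.04%, percentile 99.4). Uba52, a ubiquitin fused to a ribosomal protein, started with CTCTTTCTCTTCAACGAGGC and the poly(A)-binding protein gene Pabpc1 with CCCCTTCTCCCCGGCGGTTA. Among initiation factors Eif4a2 had a TOP start and Eif1 did not, and among androgen response genes Sord had one and Abcc4 did not. The TOP lists were assembled from mRNAs known for such starts, so their shares are not independent of how they were chosen, and without genes of those lists 3 of 31 initiation factors had a TOP start (9.68%) and the list did not stand apart (percentile 98.8), an alternative chosen after the data were seen.

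In the 42 ribosomal protein mRNAs without a TOP start, a first TOP sequence lay at base 2 in 9, at base 3 in 6, among them Rpl10 with GTCTCTTTTCCTCTGGCGCG, at bases 4 to 50 in 16 and after base 50 in 3, while 8 had none in the 5' UTR. Within the first 3 bases 52 of 79 ribosomal protein mRNAs (65.8%) had one, against 6.09% of the 8670 other genes. Where none began there, the first began at bases 4 to 50 in 16 of 27 and in 37.2% of other genes, which differ in length, and no test was made of this. Btf3 of the other TOP mRNAs started with CTCTAGCTGCCATCTTGCGT, with too few pyrimidines in a row. No TOP start was found in the 75 mitochondrial ribosomal protein, 41 spliceosome or 32 proteasome mRNAs, none of which stood apart at this number of genes. With at least 7 pyrimidines after the C, initiation factors (percentile 98.3) and androgen response genes (percentile 41.9) did not stand apart, nor did androgen response genes with a TOP start anywhere in the first 3 bases (87.2). The TOP sequence and reads of Rps27 were listed identically for Rps27rt, an almost identical gene, with 836 reads each, so these 2 cannot be separated. This pair was chosen after its values were seen.

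Over all genes the first base was G in 83.3%, A in 8.40%, C in 6.62% and T in 1.69%. Among the 79 cytosolic ribosomal protein mRNAs 41 began with C, 30 with G, 6 with T and 2 with A.

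**Figure D2:**
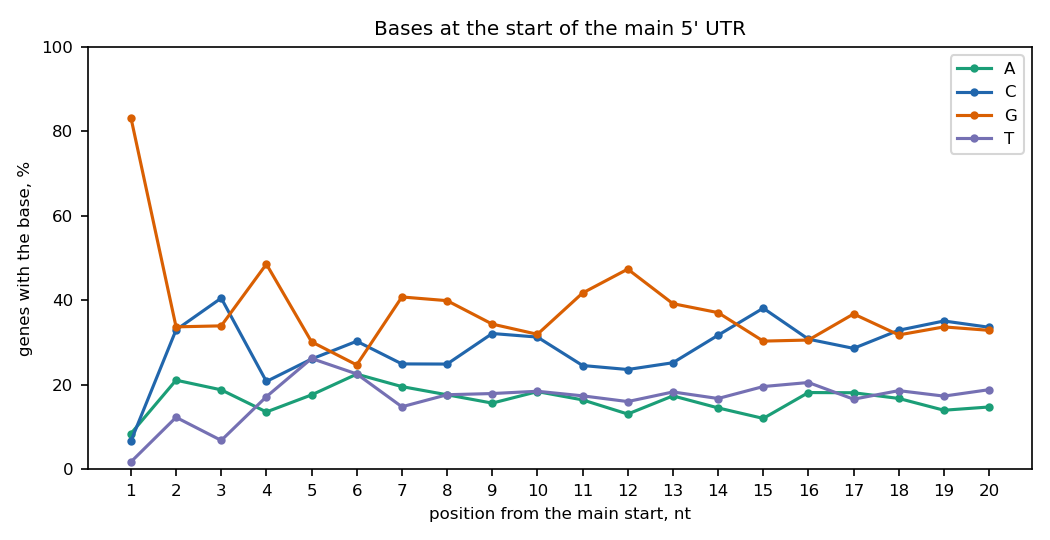
Percentage of genes with A, C, G or T at each of the first 20 positions of the 5' UTR from the start with the most reads, counted from 1 at the start. G stands at 83.3% at position 1 and at 33.7% at position 2.

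Upstream AUGs were rarer than in random lists in 10 of 27 lists and more frequent in 4. Over all genes 3082 (35.2%) had at least 1. Oxidative phosphorylation had 1 of 76, Ndufv2 with 6 AUGs. Spliceosome mRNAs had 2 of 41, cytosolic ribosomal proteins 4 of 79, chaperones 3 of 41, aminoacyl-tRNA synthetases 1 of 23, DNA replication 5 of 46, mitochondrial ribosomal proteins 12 of 75 and the proteasome 5 of 32. Glycolysis and other TOP mRNAs had 0 of 18 and 0 of 20. All 10 of these lists lay below percentile 1. Initiation factors, with 7 of 37 (18.9%, percentile 1.68), did not stand apart.

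Nuclear receptors carried an upstream AUG in 14 of 18 mRNAs (77.8%, percentile 99.97), receptor tyrosine kinases and growth factors in 15 of 23 (percentile 99.8), chromatin regulators in 30 of 56 (percentile 99.7) and stress-translated mRNAs in 9 of 13 (percentile 99.1). The stress-translated list was assembled from mRNAs known for their 5' UTRs, so its share is not independent of how it was chosen. Thrb, a thyroid hormone receptor, had 7 upstream AUGs, Tgfb3 had 8, Hdac5 had 10 and Slc35a4 had 11. Cebpb had 3, of which 2 were in frame with the coding sequence without a stop. Those 2 could therefore also be start codons of a longer protein, which was not examined. Nr1h4, Areg, Chd4 and Eprs had 0. Estrogen response genes (54.2%, percentile 96.9), PI3K-AKT-mTOR signalling (48.4%, percentile 93.2) and patterning transcription factors (37.8%, percentile 63.0) did not stand apart. Without 5' UTRs under 20 nt, stress-translated mRNAs (percentile 98.5), mitochondrial ribosomal proteins (1.41) and the proteasome (1.89) did not stand apart. The proteasome did not either with only AUGs followed by a stop (percentile 1.29) or against lists matched on reads, chosen after the data were seen (8.64).

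With matching on length 6 lists were low and none was high, and mitosis genes were among the 6 although they had not stood apart without matching (percentile 6.75). Spliceosome mRNAs had 4.88% against 24.4% in random lists of like length, oxidative phosphorylation 1.32% against 11.8%, glycolysis 0% against 27.8%, chaperones 7.32% against 24.4%, other TOP mRNAs 0% against 20% and mitosis genes 25% against 41.7%. Srsf5 with 2 AUGs, Tcp1 with 1 and Cdkn2c with 3 were the highest members named for the spliceosome, chaperones and mitosis genes. In glycolysis even Hk2, with a mean 5' UTR of 455.6 nt, had 0, a gene chosen after its values were seen. Nuclear receptors stood at percentile 79.7 and cytosolic ribosomal proteins at 3.44. With only AUGs that have a purine at position −3, oxidative phosphorylation (percentile 1.27), other TOP mRNAs (percentile 2.04) and chaperones (percentile 2.02) did not stand apart, and with only AUGs followed by a stop, mitosis genes (percentile 2.33) did not. These random lists were not matched on reads, and with matching on both length and reads, chosen after the data were seen, chaperones did not stand apart (percentile 1.94) and the other 5 lists did.

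**Figure D3:**
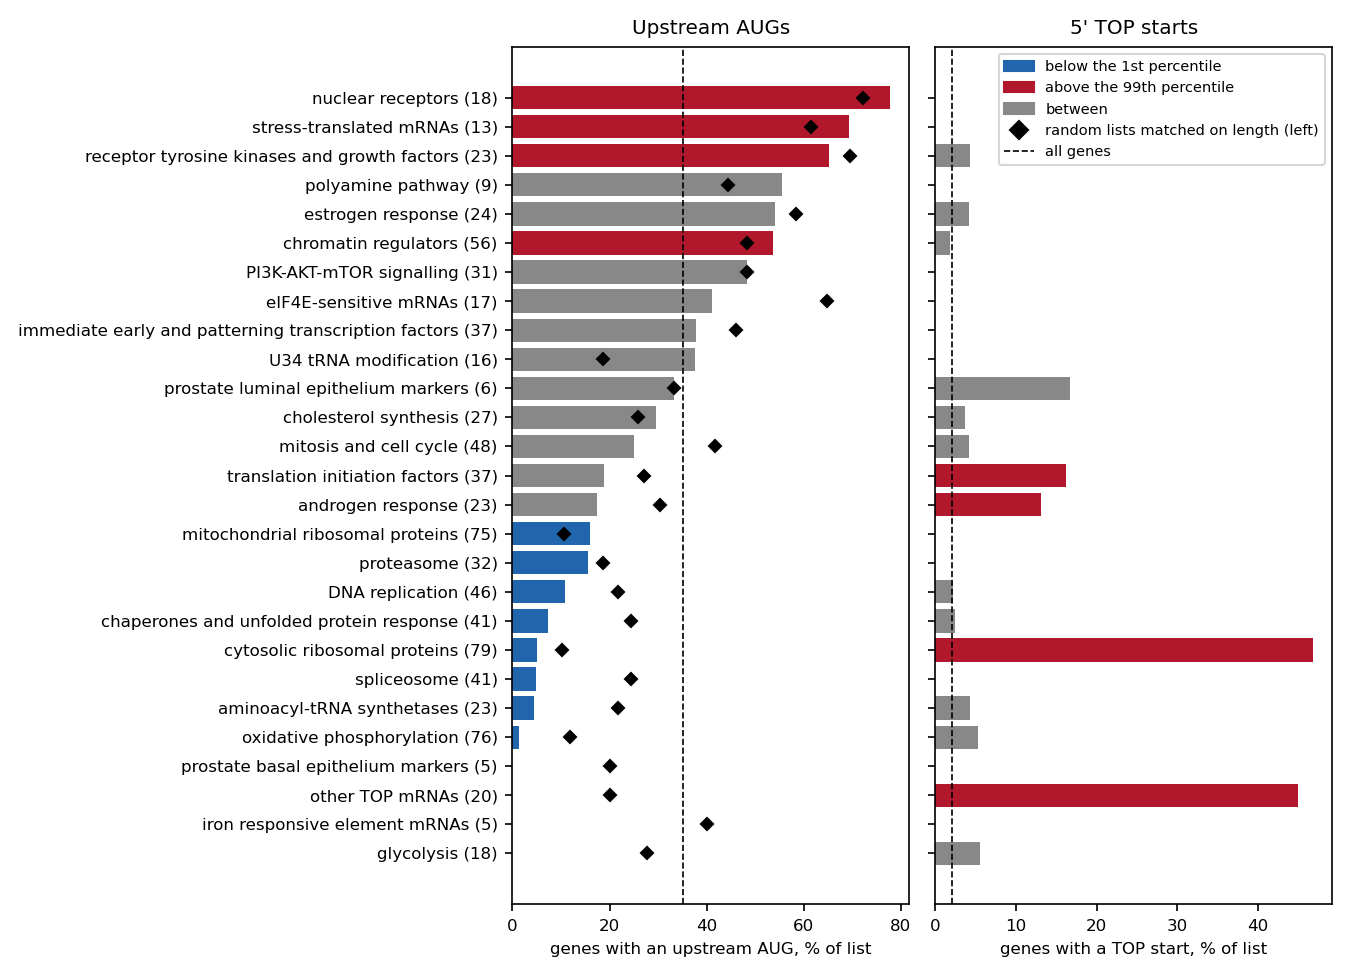
Percentage of genes with at least 1 upstream AUG (left) and with a 5' TOP start (right) in each of 27 gene lists, with the number of genes in brackets, where diamonds mark random lists matched on length and dashed lines all genes (35.2% and 2.03%). Nuclear receptors reach 77.8% with an upstream AUG, and cytosolic ribosomal proteins and other TOP mRNAs reach 46.8% and 45.0% with a TOP start.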

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

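Percentiles were compared for lists that stood apart in some setting. Under an alternative, 474 kept their side of the thresholds, 60 lost a call on the same side, 28 gained one and 8 changed sides. The 474 include percentiles without a call in either setting. Taking the longest or shortest transcript could change only 144 genes, so agreement there says little. The cause of the changes was not tested. The short lists of cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, the proteasome and DNA replication stood apart in length under every alternative run. The long list of receptor tyrosine kinases and growth factors did too. With genes of at least 220 reads, fewer genes were left, and 9 of 25 lists stood apart in length in place of 14 of 27, 3 of them long in place of 6. In folding energy 9 stood apart in place of 14, 4 of them low in place of 7, and with matching on length 2, of which 1 was low, in place of 1 and 0. Without genes in more than 1 list, initiation factors changed sides in length (percentile 80.7). In GC content 2 lists then stood apart in place of 1, 1 of them high in place of 0, and in length-matched folding energy 2, both high, in place of 1.

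In GC content 1 list stood apart, and it was low. Without 5' UTRs under 20 nt none (0) did, nor with unmatched random lists (0), chosen after seeing the data. With means in place of medians 3 did, all low, and with random lists matched on length 2 did, both low. In folding energy, random lists matched on length and GC content left 1 list, with 0 low and 1 high in place of 7 and 7. Oxidative phosphorylation then stood on the other side of the middle (percentile 21.8), as did stress-translated mRNAs (79.8), estrogen response (71.3), nuclear receptors (93.99) and receptor tyrosine kinases and growth factors (73.3). Divided by length, folding energy set 8 lists apart, 2 of them low, and stress-translated mRNAs stood at percentile 61.4, also on the other side. In length-matched folding energy 2 lists, both high, stood apart without 5' UTRs under 20 nt and also without those over 1000 nt, and 4, of which 1 was low and 3 high, with means and with energy divided by length. Cytosolic ribosomal proteins were not among the 4 with means (percentile 95.2).

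With at least 7 pyrimidines after the first C, 2 lists stood apart in TOP starts, both high, in place of 4, and androgen response genes stood at percentile 41.9. Without genes of the 2 TOP lists, chosen after seeing the data, 1 of 25 lists stood apart, and it was high. Counts of lists for upstream AUGs moved by at most 1.5 times under each alternative run. Without 5' UTRs under 20 nt the Spearman coefficient across genes was −0.177 in place of −0.155 for length with GC content and −0.966 in place of −0.973 for length with folding energy. No paired analysis was possible because there is 1 group. Replicates left out in turn, annotated 5' UTRs, several starts per gene and deposited folding energies were planned where the table held them and were not run.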

Other observations

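The motifs, genes and tests in this part were chosen after the data were seen. The test of reads in ribosomal protein genes with few pseudogenes and the 3 tests on upstream AUGs had their possible outcomes set down before their results were known, and the other tests were set after. The bases before the start codon differed between lists. The bases S-A-A-S, where S is C or G, stood directly before the start codon in 23 of 79 cytosolic ribosomal protein mRNAs (29.1%), against 12.7% in random lists of like length, above all of them. They also stood there in 19 of 76 oxidative phosphorylation mRNAs (25%, percentile 99.5), 5 of 18 glycolysis mRNAs (27.8%, percentile 99.4) and 7 of 24 estrogen response mRNAs (29.2%, percentile 99.7). Mitochondrial ribosomal proteins (12 of 75, percentile 47.2) and the proteasome (5 of 32, percentile 71.3) did not stand apart. A purine at position −3, the base that most affects start codon recognition, was found in 87.2% of genes, and in 41 of 41 spliceosome (percentile 99.8), 75 of 76 oxidative phosphorylation (percentile 99.8) and 77 of 79 cytosolic ribosomal protein mRNAs (percentile 99.4). A loose pattern for a G-quadruplex, GG 4 times with 1 to 7 bases between, was found in 49.6% of genes. Longer runs of G were not required, and folding into a quadruplex was not examined. It was found in 40 of 56 chromatin regulators (percentile 99.1) and 1 of 16 U34 enzymes (percentile 0.12). None of 27 lists stood apart in GGC repeated 4 times, which 181 genes carried. Mitosis genes, with 0 of 48, stood at percentile 15.95, so a low call was out of reach there.

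The mean length and the length at the highest peak differed by a median of 6.32 nt, and by over 50 nt in 291 genes (3.33%). They differed by over 150 nt in 35 genes, among them Tgfb1 (mean 540.0 nt, peak 866 nt), Tgfb2 (740 and 1218 nt), Trim28 (218.0 and 12 nt), Akr1a1 (238.0 and 66 nt), Atp5j (218.7 and 56 nt) and Syvn1 (275.2 and 508 nt), so for these the folding energy and upstream AUGs describe 1 of several starts. TOP starts outside both TOP lists were found in 132 genes, and those with the most reads were the galectin gene Lgals1 (20551 reads), the chaperone gene Hsp90ab1 (14976), St13 (12748) and Tubb5 (6771). The loop pattern of an iron responsive element was taken as a C followed after 5 bases by CAGWGH. It began at base 11 in Fth1, 39 in Ftl1 and 96 in Slc40a1. Aco2 and Sdhb, with 7 and 16 nt at the highest peak, had none. Being in the list does not show that mouse Sdhb carries the element, which was not checked. The same pattern was found in 809 of the 8744 other genes (9.25%), and no test was made.

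G was the first base of the main start in 83.3% of genes. A candidate explanation is a G added to every start by the library chemistry. If such a G was kept in the sequences, no ribosomal protein mRNA would have a TOP sequence at base 1. Of these mRNAs 37 had one, while 4 had a G followed by a TOP sequence. Whether base 1 was sequenced or taken from the genome is not stated in the sources used here, so these counts cannot decide. Start sites picked on few reads were argued against by the 82.5% of G among the 875 genes with the most reads. Template switching at G-rich places, or a G added to all or only some starts, stays open, because the bases before the start are not in the sequences used here. No biological explanation was tested, since the design holds 1 group.

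Genes with many reads carried fewer upstream AUGs. The share was 45.9% in the 875 genes with the fewest reads and 19.0% in the 875 with the most, whose median lengths were 138.8 and 88.0 nt. Shorter 5' UTRs did not fully account for the low share of the genes with the most reads. It lay below all 10000 random lists of like length (percentile 0, random median 29.0%). That random median was itself below the 35.2% over all genes, so length may account for part of the difference. Without genes of the fixed lists the share was 20.5% (percentile 0). Within the 4375 genes of at least 220 reads the random median was 26.2% (percentile 0). These values argue against those lists, or wrong starts of genes with few reads, as the only reason, and a part played by either stays open. No biological explanation was tested, since the design holds 1 group.

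Cytosolic ribosomal proteins are needed in about equal numbers in ribosomes, yet reads ranged from 60 in Rps12 to 22468 in Uba52, and 42 of 79 mRNAs lacked a TOP start. A candidate explanation is that reads shared with pseudogene copies were lost. Rps12 and Rpl31, with 60 and 71 reads, had 23 named pseudogenes each, the most of any and the reason for the test, and genes with more pseudogenes had fewer reads (Spearman −0.37 across 79 genes, percentile 0.06 among 10000 shuffles, and −0.32 without these 2, percentile 0.22). Other genes went the other way: Rpl21, Rpl19 and Rps11 had 15, 12 and 5 named pseudogenes and 5009, 5090 and 5914 reads. Loss of shared reads was not general either, because the almost identical Rps27 and Rps27rt were both listed, with 836 reads each. Of 24 genes with at least 5 pseudogenes 6 had a TOP start, against 31 of the other 55 (percentile 0.525). Few reads may also play a part, because mRNAs without a TOP start had a median of 733 reads against 2579 with one (percentile 0.155), and within the 55 genes 780 against 2762 (percentile 0.23). Neither test separates lost reads from starts that truly differ, pseudogenes without the parent's name were not counted, and no biological explanation was tested.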
